A study of Setaria viridis with 5 samples.

How the data were processed

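RNA-seq libraries were made from pools of about 10 hand-dissected inflorescence primordia of the grass Setaria viridis, collected at 15 days after sowing. There were 3 libraries of the wild-type reference line A10.1 and 2 of the bristleless1 (bsl1) mutant, which, per the labels, came from chemical mutagenesis followed by a backcross to A10.1 and selfing. The labels describe the pools as biological replicates, polyadenylated RNA was enriched with oligo-dT beads, and a directional library kit was used. The authors deposited 1 table of 35214 genes with both an estimated count of fragments and an FPKM value (fragments relative to transcript length and library size) for every gene in every library. Reads were processed with TopHat2 2.1.0 and Cuffdiff 2.2.1, per the submitters' processing notes. The genome build, the strand setting and the way library size and transcript length entered the FPKM values are not given in the sources used here. The deposited estimated counts were whole numbers for all but 0.716% to 0.775% of the values in each library, zeros included, or 1% to 1.15% of the values above 0. A value counted as whole only where it equalled a whole number exactly (a tolerance of 0). The FPKM values do not carry 1 transcript length per gene across libraries. An implied length was obtained by dividing fragments by FPKM. For genes of 4000 bases or more, its median was 5940 bases in bsl1 mutant replicate 1 and 4525 in bsl1 mutant replicate 2. In wild-type replicates 1, 2 and 3 it was 5626, 4894 and 4380, so the spread did not follow genotype. For genes of 1200 to 1800 bases it was 1224 in wild-type replicate 2 and 1533 to 1623 in the other libraries. A change in FPKM can therefore differ from the change in fragments of the same gene.

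The estimated counts were rounded to whole numbers and used for the main test. Totals ran from 25393087 to 49162793 fragments per library, and 7771 genes had no fragment in any library. Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3 at its minimum count of 10, which left 20498 genes (58.2%), and libraries were scaled with TMM factors. The genotypes were compared with edgeR's quasi-likelihood test over all 5 libraries with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Abundances are given as CPM, the count of a gene per 1e+06 counts of the library after TMM scaling. A second, descriptive count took genes with at least 2-fold higher (or lower) CPM in every mutant library than in every wild-type library and at least 1 CPM in every library of the higher group. A rank or permutation test of 3 libraries against 2 cannot give a one-sided p below 0.1, so none was run on single genes.

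The design fixed before the data were examined held a choice for FPKM and one for counts. As the table held both, the count test was used, and limma 3.58.1 on log2(FPKM + 1) for genes with a mean of at least 1 FPKM became an alternative. Other alternatives fixed at that point were DESeq2 1.42.0, median-ratio scaling, no filter on low counts, stricter calls, other pseudocounts, filters, scalings and weights in the FPKM fit, a replicate block and leaving out each library. Weights per library in limma voom, a robust fit, a correction for implied gene length, thinning of all libraries to the smallest total, total-count scaling and a minimum of 5 CPM were added after the data were seen. The main test was tested on simulated data made from the means, depths and dispersions of these libraries, with 20253 genes passing the filter. It recovered 13.3% of 98 genes changed 2-fold and 68.4% of 98 genes changed 4-fold, with 8 unchanged genes called. DESeq2 on the same simulated counts recovered 55.1% and 84.7%, with 79 unchanged genes called. The simulated genes were drawn independently, with the same dispersion in both genotypes. Differences between libraries that many genes share were left out, so these shares may not hold for the real libraries.

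Replicate numbers 1 and 2 occur in both genotypes, but no label says that they mark a shared day or batch, so they were not treated as pairs. Files used here give gene identifiers of the v1.1 annotation without names or descriptions. The reference gene table, made for another assembly, contained 0 of these identifiers. The gene lists fixed beforehand (hormone pathways, meristem and floral regulators, cell wall, cell cycle, stress and markers of leaf, anther and vascular tissue) and the enrichment of annotation terms could therefore not be applied, and no gene is named here beyond its identifier. The rule for named genes took the 10 genes with the smallest p when fewer than 10 passed the threshold. Of these, identifiers are printed for both genes that passed and for the 1 gene that was lower in the mutant. The chromosome is read from the identifier, and positions in bases are not given.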

Results

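Transcriptomes of young Setaria viridis inflorescences were compared between the bsl1 mutant and the wild-type line A10.1. Setaria inflorescences carry sterile branches called bristles beside the spikelets, and the mutant is named for their absence. The study, by its title, asks how brassinosteroids, a class of plant steroid hormones, act on meristem fate in this inflorescence. The comparison addresses which genes differ in transcript abundance in primordia dissected at 15 days after sowing. The 3 wild-type libraries held 44739001, 32946287 and 25393087 fragments, and the 2 mutant libraries held 49162793 and 34069429. Between 19015 and 21216 genes had at least 10 fragments in a library. The mutated gene was not identified here, because the identifiers used carry no gene names, and its abundance is therefore not given as a check of the labels.

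The 2 mutant libraries resembled each other more than any other pair did. Among genes of at least 3 on the log2 CPM scale, the median absolute difference between them was 0.0775 on the log2 scale. Over all tested genes, which are not independent replicates, their log2 CPM values correlated at r = 0.992. The wild-type libraries were more spread. Wild-type replicates 2 and 3 differed by a median of 0.141, while wild-type replicate 1 differed from them by 0.23 and 0.279. Wild-type replicate 1 was closer to the mutant libraries, at medians of 0.165 and 0.18, than to either library of its own group by this measure. By correlation of log2 CPM, which took all tested genes, it was no closer to them (r = 0.972 and 0.973) than to wild-type replicate 2 (r = 0.973). Its correlation with wild-type replicate 3 was 0.952. The first principal component held 51.7% of the variance and placed wild-type replicate 1 (score -35.75) with the mutant libraries (-41.51 and -27.25) and away from wild-type replicates 2 and 3 (28.59 and 75.92). The second component, with 30.1% of the variance, gave both mutant libraries higher scores (34.8 and 31.3) than the wild-type libraries (-55.37, -23.94 and 13.21). The labels give 5 separate pools. No pair agreed within counting noise (the smallest chi-square per degree of freedom, between the mutant libraries, was 9.21), so none was merged as 1 library deposited in duplicate.

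**Figure D1:**
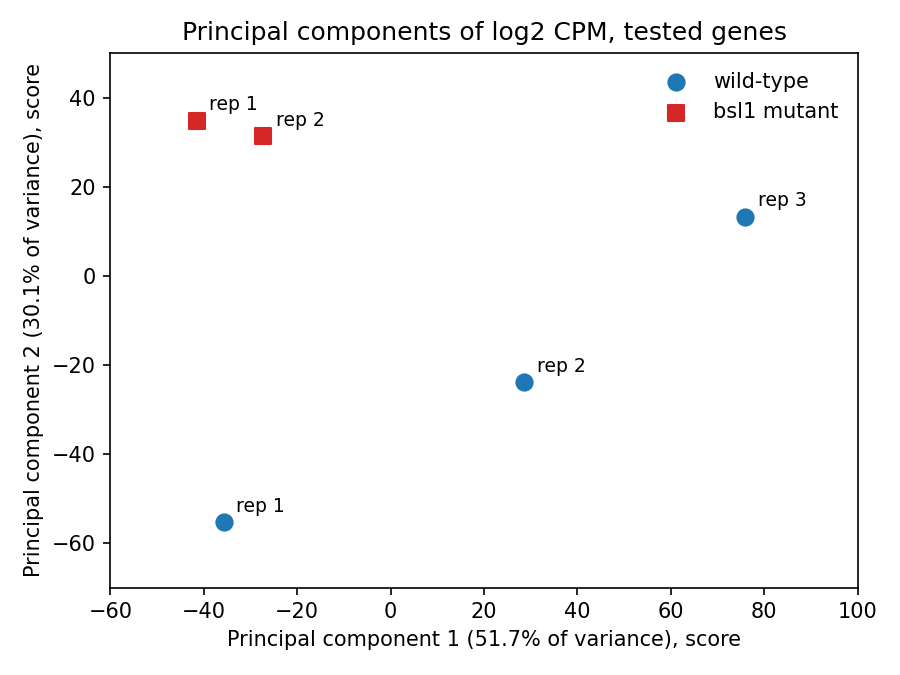
Scores of the 5 libraries on the first and second principal components of log2 CPM over the tested genes; circles are wild-type libraries, squares are bsl1 mutant libraries, and numbers are replicates. The mutant libraries lie together (first-component scores of -41.51 and -27.25), and the wild-type libraries spread from -35.75 to 75.92.

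Transcripts of 2 genes rose in the mutant and none fell at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Sevir.9G319500, on chromosome 9 by its identifier, rose 28.9-fold, from 1.31 ± 0.235 CPM (SD, n = 3) in wild-type to 38.2 ± 6.64 CPM (SD, n = 2) in the mutant. Its log2 fold was 4.85 with a standard error of 0.211, and its edgeR adjusted p was 0.0177. Wild-type libraries held 69, 40 and 28 fragments of this gene and mutant libraries 1677 and 1507. Sevir.7G140700, on chromosome 7 by its identifier, was already well expressed in wild-type primordia, at 50.3 ± 6.54 CPM (SD, n = 3), and rose 6.22-fold to 313 ± 10.5 CPM (SD, n = 2). Its log2 fold was 2.64 with a standard error of 0.132, and its edgeR adjusted p was 0.019. Both genes kept their direction in all 22 alternatives, and both were called with wild-type replicate 1 left out. Leaving out any of the other 4 libraries ended both calls, with edgeR adjusted p-values of 0.171 to 0.393, and the fit with a replicate block ended them at 0.0835.

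The next genes by p-value missed the threshold. Of the 10 genes with the smallest p, 9 were higher in the mutant and 1 was lower, and the largest edgeR adjusted p among them was 0.0574. The 7 of them not named here were 2.59-fold to 36.5-fold higher in the mutant. The lower one was Sevir.2G397400, on chromosome 2 by its identifier, at 3.19 ± 0.503 CPM (SD, n = 3) in wild-type and 0.17 ± 0.042 CPM (SD, n = 2) in the mutant, a log2 fold of -4.23 with an edgeR adjusted p of 0.0574. Each mutant library held 7 fragments of it and the wild-type libraries 127, 95 and 94. At an unadjusted p under 0.05, 1559 genes were higher and 304 lower, and leaving out wild-type replicate 1 moved these counts to 3062 and 2218. DESeq2, which called 79 unchanged genes in the simulated data against 8 for edgeR, called 531 higher and 55 lower, both edgeR calls among them. With wild-type replicate 1 left out, edgeR called 766 higher and 254 lower, again with both. DESeq2 and that fit shared 374 genes, out of 586 and 1020.

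**Figure D2:**
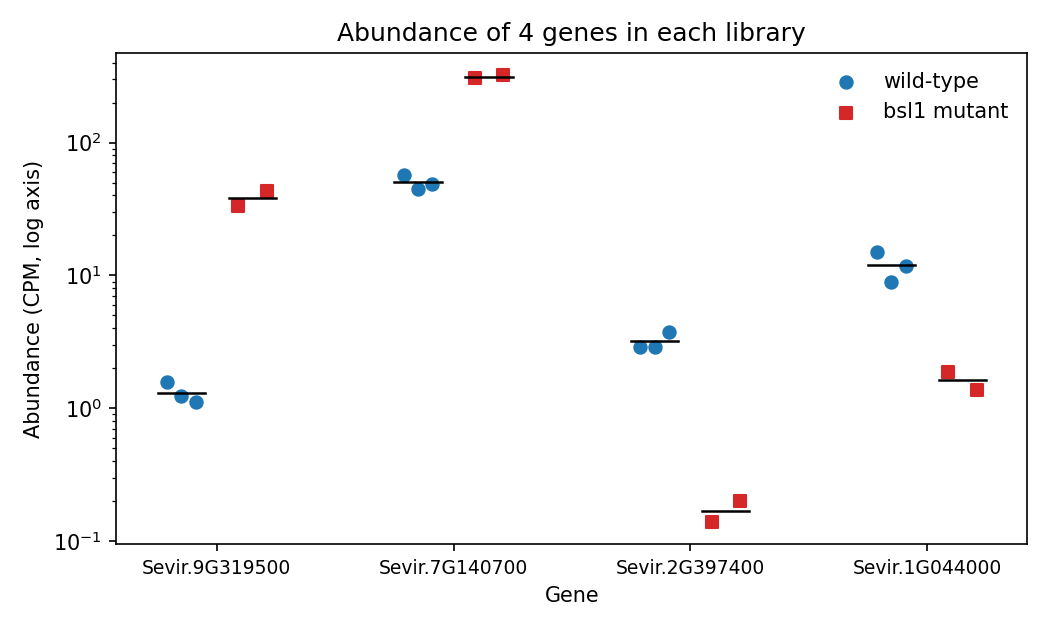
Abundance in CPM, on a log axis, of 4 genes in each wild-type library (circles) and each mutant library (squares), with the group mean as a line. Sevir.9G319500 and Sevir.7G140700 passed the edgeR threshold with 28.9-fold and 6.22-fold rises, and Sevir.2G397400 and Sevir.1G044000 were lower in both mutant libraries without passing it.

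Genes with clearly separated libraries lay almost entirely on the higher side of the mutant. CPM was at least 2-fold higher in every mutant library than in every wild-type library for 206 genes, and at least 2-fold lower for 3. At 4-fold the counts were 38 and 2. The 2-fold counts were 91 and 2 with a minimum of 5 CPM, and 123 and 5 on FPKM values. The 206 genes were weakly expressed in wild-type primordia, with a median of 0.829 CPM against 4.87 CPM in the mutant, and 88 of them were under 1 CPM in every wild-type library. Across all tested genes the wild-type median was 17.3 CPM. Wild-type replicate 1, which lay with the mutant libraries on the first principal component, was a median of 0.203 on the log2 scale above wild-type replicates 2 and 3 for the 206 genes, against 0.00225 for all tested genes. The median log2 fold of the 206 genes was 2.14, while over all tested genes it was -0.0138. The genes came from all 9 numbered chromosomes, from 0.806% of the tested genes of chromosome 1 to 1.37% of those of chromosome 7. DESeq2 called 180 of the 206, and edgeR without wild-type replicate 1 called 160. The 206 were chosen for their gap in the same counts, so these calls are not separate support. Without a minimum fold, 16.6% of tested genes were higher and 11.6% lower in every mutant library than in every wild-type library. Exchangeable libraries would give 10% in each direction on average. Genes that move together can take a single split far from that average, and these shares were not computed for other splits.

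The 3 genes on the lower side include Sevir.2G397400. Another, Sevir.1G044000, chosen for mention after its values were seen, was at 11.9 ± 3.1 CPM (SD, n = 3) in wild-type and 1.62 ± 0.362 CPM (SD, n = 2) in the mutant, a log2 fold of -2.86 with an edgeR adjusted p of 0.0793. The third had a fold of 3.69 toward wild-type and an edgeR adjusted p of 0.0874. The separated counts depend on which libraries are compared. Setting wild-type replicates 2 and 3 against the other 3 libraries gave 26 genes at least 2-fold higher and 179 at least 2-fold lower. That is 205 in all, against 209 between genotypes. Both mutant libraries are among those 3, so this split is not free of genotype. Leaving out wild-type replicate 1 gave 490 higher and 34 lower genes between genotypes. Leaving out mutant replicate 2 gave 467 and 7, and leaving out wild-type replicate 3 gave 284 and 40. Leaving out mutant replicate 1 gave 292 and 13.

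**Figure D3:**
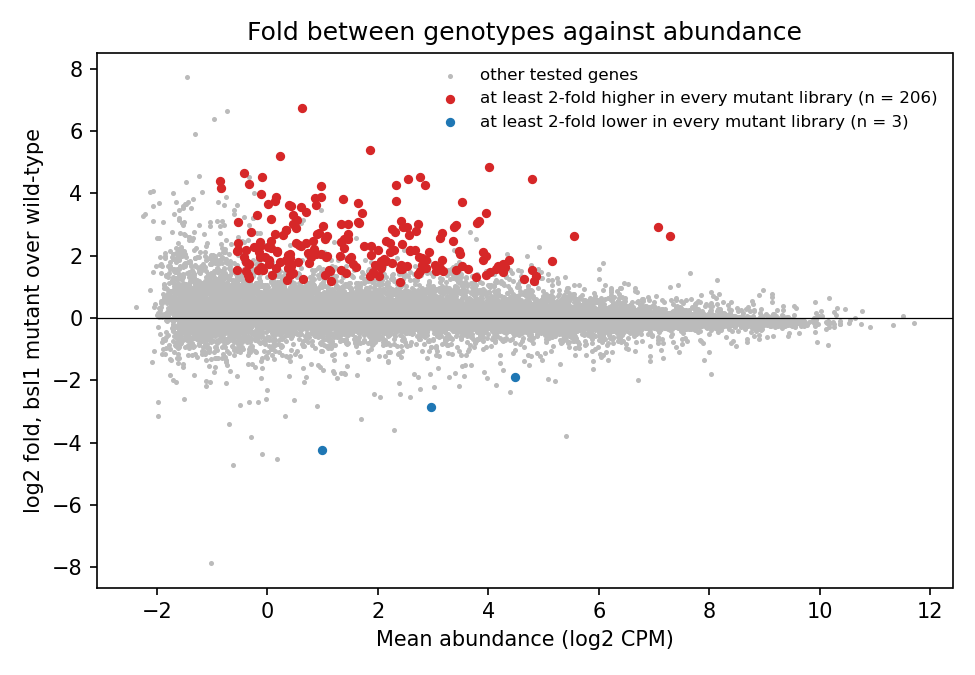
Log2 fold of the mutant over wild-type against mean abundance in log2 CPM; each point is a tested gene. The 206 genes at least 2-fold higher in every mutant library lie mostly at low abundance, and 3 genes were at least 2-fold lower.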

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

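The library quality weights in limma voom, the robust fit, the length correction, thinning, total-count scaling and the 5 CPM minimum were chosen after the data were seen. The edgeR counts of 2 higher and 0 lower genes were the same with median-ratio factors, a minimum of 2-fold, the robust fit, the gene-length correction and thinned libraries. Without the filter on low counts they were 48 and 4, with DESeq2 531 and 55, and with library quality weights 884 and 147, where wild-type replicate 1 had a weight of 0.19 and the mutant libraries 2.09 and 2.05. An adjusted p under 0.01 left 0 and 0. In limma on FPKM there were 6 and 0 with pseudocount 1, with or without the trend, 1 and 0 with 0.1, 0 and 0 with 0.01, with no filter, with median-ratio factors or with quantile normalization, 3 and 0 at a mean of at least 5, and 14 and 1 with array weights. Fits that left out 1 library gave 0 to 766 higher and 0 to 254 lower genes, and the upper end is the fit without wild-type replicate 1 (3062 and 2218 at an unadjusted p under 0.05); the other 4 gave 0 and 0, with 658 to 1514 higher and 51 to 422 lower genes at an unadjusted p under 0.05. Fits with 1 mutant library assume that it varies like the wild-type libraries. The replicate block gave 0 and 0, with 1492 and 397 genes at an unadjusted p under 0.05, and edgeR adjusted p-values of 0.0835 for Sevir.9G319500 and Sevir.7G140700. No label says that the numbers mark a shared batch. Deviations of same-numbered libraries from their group means correlated at 0.163 and -0.0341. With 2 mutant libraries the deviations of 1 mirror those of the other, so these values cannot settle whether the libraries were paired. The 206 and 3 genes at least 2-fold apart became 123 and 5 on FPKM and 91 and 2 at 5 CPM, and ranged from 254 to 490 and from 3 to 40 when 1 library was left out, as fewer libraries had to agree. Without the filter, with either other scaling and after thinning they were 200 to 237 and 3 to 4. Sevir.9G319500 passed the threshold in 13 of 22 alternatives (log2 fold 3.63 to 5.09) and Sevir.7G140700 in 12 of 22 (2.46 to 2.76), and neither changed sign. Sevir.2G397400 passed in 4 of the 14 alternatives that tested it (log2 fold -4.54 to -1.07), and Sevir.1G044000 in 5 of 22 (-3.12 to -2.28). The cause was not tested. Alternatives for gene lists and annotation terms were not run, as no identifier matched a name. In simulation with genes drawn independently, the edgeR threshold recovered 13.3% of 2-fold changes.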

Other observations

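The thinning and length-correction tests and the tests on shared fragments and an extra copy were set out before their results were seen, and counting shared genes in the first 2 was decided afterwards. The tests of scaling, of other splits and of gene order were chosen after the patterns were seen. A pattern not described above appeared along the chromosomes. Among 13130 genes with at least 3 on the log2 CPM scale, put in the order of their identifiers, the running median of the log2 fold over 15 genes was highest on chromosome 8, at 0.502. It came from 10 consecutive genes of that abundance, the 488th to the 497th of 546 on that chromosome, with serial numbers 219500 to 222700 in the v1.1 identifiers. The edges were set from the log2 folds themselves. The run is the widest stretch around the peak that began and ended at 0.3 or more with at most 1 gene below. By that rule 9 of the 10 genes had a log2 fold above 0.3, and 8 were higher in both mutant libraries than in every wild-type library. Their median fold was 1.46 (log2 0.542, range 0.0209 to 1.07), while the 17 flanking genes had a median log2 fold of -0.115. As the edges follow the folds, this contrast is not separate support for the run. The median log2 difference from the wild-type mean over the 10 genes was 0.482 and 0.653 in the mutant libraries and 0.0208, 0.0949 and -0.0558 in wild-type replicates 1, 2 and 3. No gene of the run passed the edgeR threshold alone (adjusted p 0.102 to 0.973), and 4 did without wild-type replicate 1.

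For this run, a chance arrangement of genes is argued against by shuffled gene orders, of which 2 in 2000 reached as high a value (permutation p = 0.0015, and 0.0045 after Benjamini-Hochberg adjustment over 3 window sizes). Shuffling treats genes as exchangeable, which neighbouring family members are not. Windows of 9 genes put the highest value, 0.649, on chromosome 5 (adjusted p = 0.018), and windows of 25 genes, over which a run of 10 cannot set the median, gave an adjusted p of 0.11. Fragments divided in fractions between overlapping or near-identical genes are argued against, as 0 of the 10 genes had an estimate that was not exactly whole (a tolerance of 0). Such values were rare in every library, at 1% to 1.15% of the values above 0, so this does not set the run apart from other genes. A shared fragment assigned whole to 1 gene would not show in this count, so sharing of that kind was not tested. A hypothesis is that the mutant line may differ from A10.1 in this segment, by an extra copy or by a linked change left from mutagenesis. An extra copy raising every gene alike cannot be told apart from other causes here: 2 of the 10 genes, at log2 folds of 1.07 and 0.0209, had 95% intervals that left out the run's median and the other 8 did not, and DNA was not measured.

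Setting wild-type replicates 2 and 3 against the rest gave about as many 2-fold apart genes as the genotypes did, and more calls. The rest held wild-type replicate 1 and both mutant libraries, so this split mixes genotype with differences among wild-type libraries. No contrast among wild-type libraries alone was run. Of the 10 splits of the 5 libraries into 2 and 3, wild-type replicates 2 and 3 against the rest gave 39 edgeR calls and 2112 DESeq2 calls, against 2 and 586 for the genotypes, so 2 of 10 splits had as many edgeR calls as the real one. For genes at least 2-fold apart, 1 of 10 splits, the real one, reached 209, and the highest other was 205. With 10 splits a share under 0.05 cannot be reached. Wild-type replicates 2 and 3 had the smallest totals, so a part for unequal depth was looked at by thinning. That split had 4297 genes with an unadjusted p under 0.05 in edgeR. After thinning every library to the smallest total, 3816 of them (88.8%) were still under it in the same direction. Most of these calls therefore did not need unequal totals in the test. Thinning leaves CPM unchanged on average and keeps the noise already present in the smallest library. It does not settle whether depth had a part, and other differences tied to depth were not tested. Gene length as the whole cause is argued against by the same count, with 3727 genes (86.7%) after the length correction. A difference in developmental stage or dissected tissue between pools may remain, and no test of it was possible without gene names. The labels give no batch.

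The excess of genes higher in the mutant was 206 against 3, and higher genes outnumbered lower ones at least 66.7 to 1 with median-ratio factors and with total-count scaling, but the TMM factors ran only from 0.981 to 1.031, too close together for these scalings to undo a 2-fold gap, so scaling stays untested. After thinning the ratio was 52.8 to 1, but CPM is already relative to depth and thinning leaves it unchanged on average. Thinning could therefore hardly have undone a 2-fold gap, and it does not settle a difference in depth. The split of wild-type replicates 2 and 3 against the rest also had an uneven 2-fold count, with 179 genes lower and 26 higher in those libraries, but it was nearly even at an unadjusted p under 0.05 (2102 higher, 2195 lower) and in DESeq2 (1084 and 1028), where the genotypes gave 1559 and 304, and 531 and 55. Wild-type replicates 1 and 3 against the rest were also uneven, on fewer genes, with 108 higher and 538 lower at an unadjusted p under 0.05, 2 and 39 in DESeq2, and 0 and 11 at least 2-fold apart. The genotypes' own unadjusted counts were more even without wild-type replicate 1 (3062 and 2218) and with library quality weights (3273 and 2220). Weakly expressed genes of another tissue or stage, more abundant in the mutant pools, may be behind it, and this, a structure of the libraries and an effect of the mutation all stay open.

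The 206 higher genes formed 10 adjacent pairs in the order of tested genes, where 10000 shuffles gave a mean of 2.05 and at most 8 (permutation p = 1e-04, the smallest these shuffles can give). Shuffling treats genes as exchangeable, which neighbouring family members are not, and pairs were not counted for other splits. None of the 19 genes in these pairs had a fragment estimate that was not exactly whole in any library (0 genes, at a tolerance of 0). Such values were rare in every library, at 1% to 1.15% of the values above 0, and shared fragments assigned whole to 1 gene would not show.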
